A study of Homo sapiens with 88 samples.

How the data were processed

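Gene expression was measured on 88 Affymetrix HG-U133 Plus 2.0 arrays in 9 small cell lung cancer (SCLC) lines. Per the labels, cells grew in RPMI with serum and received the vehicle DMSO or a treatment that the titles call 552A. The treatment protocol names DMSO and 1 µM of GSK2879552, an inhibitor of the histone demethylase LSD1, which the gene KDM1A encodes. No label says that 552A stands for that compound, so the arm is called 552A throughout. SHP-77, NCI-H526, NCI-H510, COLO668, NCI-H146 and NCI-H446 were sampled at days 2, 4 and 7, and H69, H2171 and H1417 at day 4. Line, treatment and day gave 42 groups, of which 39 held 2 arrays, 2 held 3 and 1 held 4.

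The deposited values were log2 expression levels per probe set. The program that made them, its background correction and its scaling are not given in the sources used here. The array medians lay between 7.36 and 7.46, a spread of 0.097, under the limit of 0.5 set for rescaling, so the values were used as the authors deposited them. No probe set was centred on 0. Arrays carry no read depth, and their number limits the precision.

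A list of gene symbols for the array assigned 1 to 41091 of the 54675 probe sets, several to 1801 and none to 11727, beside 62 control probe sets. No symbol needed an update through its Entrez ID, and 54 probe sets had an ID with no match. Controls and probe sets with several symbols or none were left out. A probe set was kept if the mean of at least 1 group lay above the median of all values, 7.41. The probe set with the highest mean over all arrays stood for its gene, after those ending in _x_at were set aside where the gene had another. HLA-B, HLA-F and IFITM3, named below, were read from a probe set ending in _x_at. Of 19775 genes with a probe set, 15352 were tested. Genes of the lists without such a probe set are not reported here.

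Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, called at an adjusted p below 0.05), with version 1.17.8 of data.table. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The response of a line was the mean over its days of 552A minus DMSO, with days weighted equally. It came from a fit over all arrays with a mean for each of the 42 groups, which left 46 residual degrees of freedom and a prior of 6.52. The shared response used 1 log2 ratio per line and day, tested against 0 with the line as the replicate. Equality of the 6 time course lines was tested with a moderated F test. SE stands for the standard error of the fit. No label says that arrays of a group came from separate cultures, so p-values within a line rest on the spread between arrays of a group, which may be technical. That spread was pooled over all lines, so arrays of 1 line also affect the calls in another.

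The 18 gene lists were tested with camera, with the preset inter-gene correlation of 0.01 and again with a correlation estimated per list. They cover neuroendocrine markers, neural and neuroendocrine transcription factors, the Notch pathway, the tuft cell program, LSD1 and its partner proteins, and myeloid differentiation. They further cover mesenchymal and epithelial genes, TGF-beta signalling, the interferon response, class I antigen presentation, cell cycle and proliferation, and cell cycle arrest with p53 targets and apoptosis. The others hold MYC family and ribosome biogenesis genes, cholesterol synthesis, amino acid and unfolded protein stress, DNA methylation and polycomb proteins, and markers of immune, fibroblast and endothelial cells. The test within each line was adjusted over 162 pairs of list and line.

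The lists, the tests and the genes to be named were fixed before the data were examined. The rule named the 10 genes per direction with the largest shared ratio at day 4 among those called and of the same sign in at least 8 of 9 lines, or the 5 with the smallest p where fewer passed. For each line it named the 2 genes per direction with the largest called change of the same sign on every day. It further named the 6 called genes whose effects had the largest range over the time course lines, a fixed set of regulators, and the 4 members of each list with the largest change. Genes outside that rule are said to be so where they appear.

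The alternatives were quantile normalization, no filter or a stricter filter on dim probe sets, the mean of all probe sets of a gene, each line or array left out, a fit at array level, a line's own arrays alone, single days, an intensity trend, the replicate number as a block, and the estimated correlation. Added after the data were seen were the removal of 6 arrays and the ACTB 3' minus 5' signal, a sign of RNA integrity, as a covariate. The 6 arrays were 5 of day 7 with that signal above 0.8, where the highest of the other arrays was 0.73 and the median over all arrays 0, and NCI-H446 DMSO day 4 replicate 2, whose interquartile range was 2.56. The 5 were SHP-77 DMSO replicate 1 and 552A replicates 1 and 2, COLO668 DMSO replicate 1 and COLO668 552A replicate 2. Every array correlated best with an array of its own line, and no arrays held identical values.

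The scripts were tested on simulated data for the 15352 genes with 200 changed. The NCI-H526 comparison recovered 94% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1, with 8 false calls. The H69 comparison, with 2 arrays against 2, recovered 53.7% at 0.5 and 97% at 1. The F test recovered 86.6% at 0.5. The shared test recovered 97% at 0.5 in 9 lines and 88.1% in 6, for effects equal in all lines. With no gene changed, the NCI-H526 comparison called 1 gene. A list shifted by 0.3 was called and 0 other lists were, with genes drawn independently of each other. This cannot show how often camera calls a list whose members are correlated. The labels place no line in the class of sensitive or resistant lines that the series mentions, so no such comparison was made.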

Results

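The arrays followed 9 established human SCLC lines under DMSO or 552A. SCLC is a lung tumour whose cells usually carry neuroendocrine markers, and the series asks how inhibition of LSD1 changes gene expression in such lines. The 6 time course lines gave 12 to 14 arrays each, and H69, H2171 and H1417 gave 4 each, so that day 2 had 25 arrays, day 4 had 37 and day 7 had 26. Levels below are log2 signals on the array, and changes are 552A minus DMSO on the log2 scale from limma. A change of at least 1 may be a lower limit where the mean of 1 arm was dim, below 6.09, the median lower quartile of the arrays. This limit was chosen after the data were seen, and the floor of each probe set was not measured. Apart from genes named as such below, 1 arm was dim for ANXA3 in SHP-77 and NCI-H146, YAP1 and ZEB1 in NCI-H510, ZNF217 in COLO668, and HEPACAM2 and SNAI2 in NCI-H446. The same applied to PTPRC and SORCS3 in NCI-H146, LRRN4 in H69, CHRNB4 in H2171, and CYP4X1, DLK1, SORCS3 and ZEB1 in H1417.

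The untreated lines differed in the regulators by which SCLC is often described. POU2F3, a transcription factor of tuft cells, had a mean signal of 12.48 ± 0.21 (SD, n = 6 DMSO arrays) in NCI-H526 and means between 4.54 and 4.79 in the others. GFI1B, a repressor that recruits LSD1, likewise stood at 11.61 ± 0.04 (n = 6) in NCI-H526 and between 7.01 and 7.46 elsewhere. MYCN was high in NCI-H526 at 12.46 ± 0.06 (n = 6) and in H69 at 11.76 ± 0.02 (n = 2). MYCL was high in COLO668 at 14.44 ± 0.13 and in NCI-H510 at 14.26 ± 0.05 (both n = 6), and MYC was highest in H2171 at 13.71 ± 0.06 (n = 2). INSM1, a neuroendocrine repressor, ranged only from 12.36 to 13.80. KDM1A itself lay between 11.44 and 12.74 under DMSO, and its transcript did not pass the test under 552A in any of the 9 lines, with a mean ratio of 0.03 ± 0.03 (SE, n = 9 lines).

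The first comparison asked which genes responded to 552A across lines, with the line as the replicate. Among the genes called at day 4 the largest shared change was that of PTPN14, a tyrosine phosphatase that binds the growth regulator YAP, which rose by 1.17 ± 0.13 (SE, n = 9 lines, adjusted p = 0.0239). NEO1, a receptor for netrins, rose by 0.43 ± 0.06 (adjusted p = 0.0270), and NCR3LG1, a ligand for a receptor of natural killer cells, rose by 0.42 ± 0.05 (adjusted p = 0.0270). Among the genes that fell was HMG20B, a subunit of the LSD1 complex with CoREST, at -0.30 ± 0.04 (adjusted p = 0.0270). Each of these had the same direction in 9 of 9 lines, although HMG20B was only at -0.027 in H2171. The same ratios chose these genes, so the shared direction is no separate evidence.

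Of 15352 genes, 8 passed in this shared test, 5 up and 3 down, while 1912 had an unadjusted p below 0.05 where 768 are expected by chance. CYFIP1, part of an actin regulatory complex, rose by 0.25 ± 0.04 and C11orf54 by 0.23 ± 0.03 (adjusted p = 0.0440 for both). FAM83F fell by 0.38 on the log2 scale (SE 0.05) and VAV2 fell by 0.25 (SE 0.03; adjusted p = 0.0270 for both). AMPD3 at -0.35 (adjusted p = 0.0531) and PRR5 at -0.24 (adjusted p = 0.0574), the next by p on that side, did not pass. The count depended on most of the lines: 0 genes passed without NCI-H510, COLO668, NCI-H146 or H69 (limma), 1 without NCI-H446 or H1417, 2 without NCI-H526, 5 without H2171 and 6 without SHP-77. The ratios themselves moved little where 0 genes passed, with PTPN14 between 1.14 and 1.19 and HMG20B between -0.30 and -0.29. PTPN14 had 4 usable probe sets, and their mean gave 0.74 with an adjusted p of 0.0835, and CYFIP1 had 0.25 with an adjusted p of 0.0741 after quantile normalization. Without the 6 arrays in doubt CYFIP1, C11orf54 and FAM83F had 0.24, 0.21 and -0.35 but did not pass, with adjusted p of 0.0621, 0.0939 and 0.0727.

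Within lines, tested against the spread between arrays, the 8 genes were called in 2 to 8 lines. Averaged over days, PTPN14 rose in 7 of 9 lines, NCR3LG1 and CYFIP1 in 8 each and NEO1 in 6, and HMG20B fell in 7, while C11orf54 rose in 4, VAV2 fell in 5 and FAM83F fell in 2. SEPTIN10, a cytoskeletal GTPase, rose in 7 lines, as did OVOL2, a repressor that maintains epithelial cells, and the keratin KRT19 rose in 6. Gastrin-releasing peptide (GRP), a growth-promoting peptide of SCLC, fell in 6 lines, and ST18, a neural zinc finger factor, and the nicotinic receptor subunit CHRNA3 also fell in 6, although CHRNA3 rose in 2 others. NKX2-2, a homeodomain factor of neuroendocrine cells, fell in 5 lines, and the secretory granule protein CHGA fell in 5. None of GRP, NKX2-2 or CHGA passed in the shared test, where GRP had a mean of -1.06 ± 0.20 (adjusted p = 0.0816) and was lower in 9 of 9 lines.

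**Figure D1:**
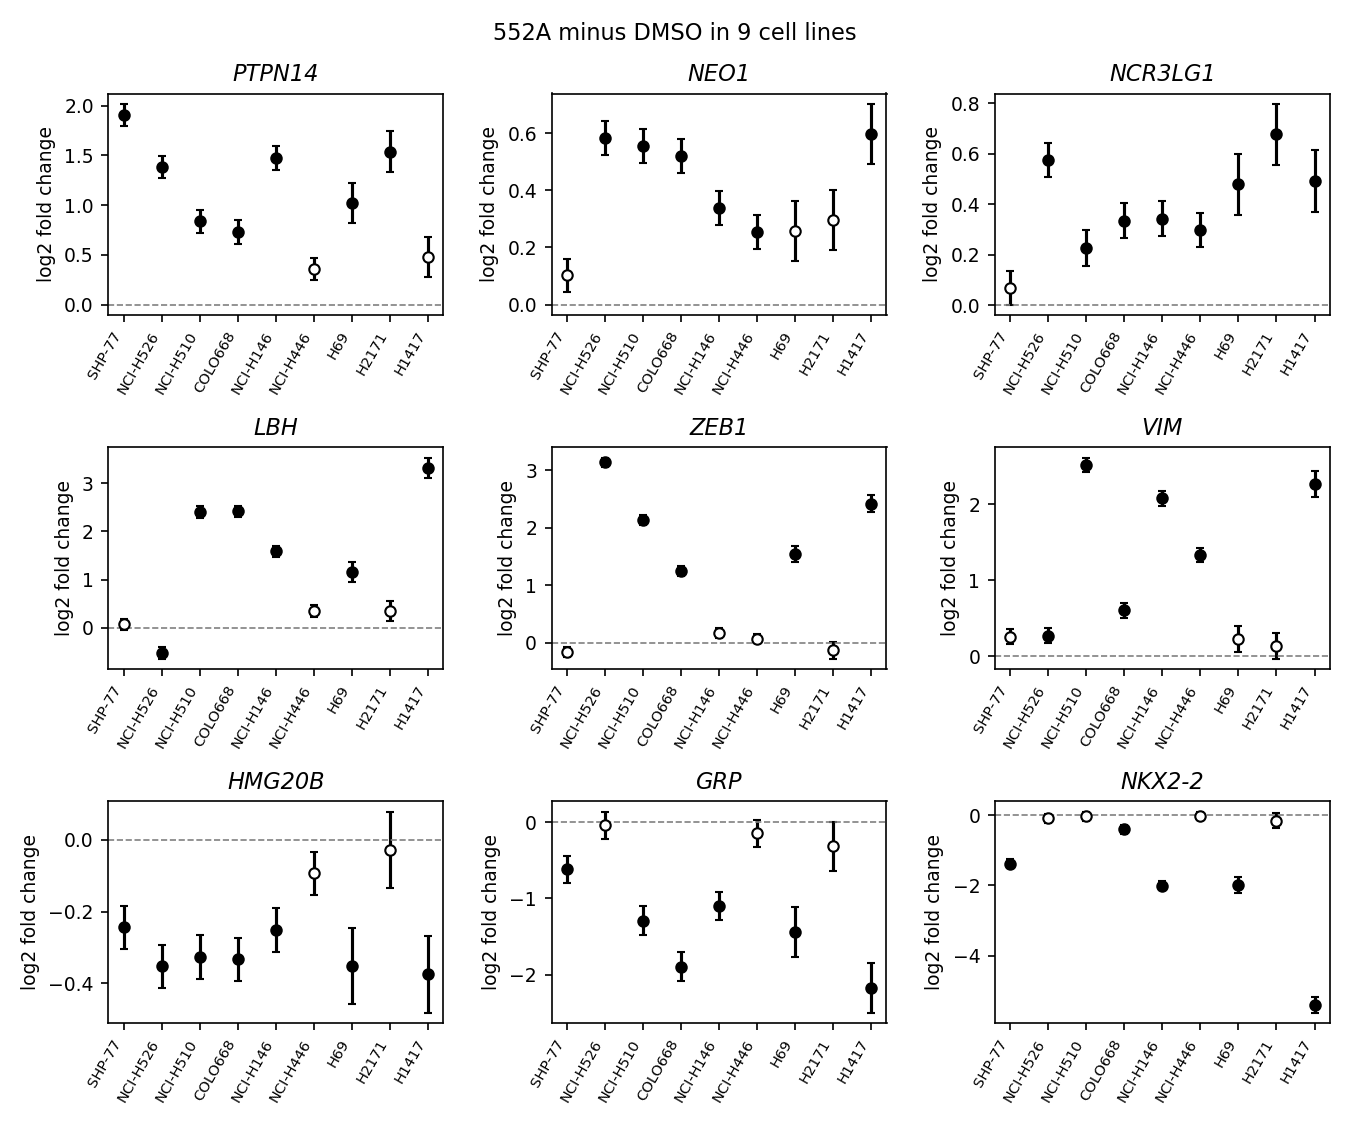
Log2 fold change of 9 genes (vertical axis, 552A minus DMSO) in each of 9 cell lines (horizontal axis), as points with bars of 1 SE. Filled points had an adjusted p below 0.05 in that line. PTPN14 lay above 0 in all 9 lines, while ZEB1 spanned -0.16 in SHP-77 to 3.14 in NCI-H526.

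Among the 18 gene lists, the mesenchymal list rose in the shared response at day 4. Its 38 members had a median ratio of 0.13 (camera adjusted p = 3.15e-05, and adjusted p = 0.00923 with an estimated correlation). None of its members passed over all genes, and 11 rose and 0 fell adjusted over the list alone. Those with the largest means were ZEB1, a repressor that drives the mesenchymal state, at 1.20 ± 0.34, the intermediate filament VIM at 1.03 ± 0.29, SNAI2, a repressor of the same kind that can bind LSD1, at 0.76 ± 0.18, and the annexin ANXA3 at 0.68 ± 0.16 (SE, n = 9 lines). VIM, SNAI2 and ANXA3 were higher in 9 of 9 lines and ZEB1 in 7.

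The neuroendocrine markers fell as a list, with a median of -0.08 over 29 members (camera adjusted p = 0.000189, adjusted p = 0.39 with an estimated correlation). None of its members passed over all genes, and 6 fell adjusted over the list alone. After GRP, the largest means were CALCA at -0.36 ± 0.13, CHGA at -0.34 ± 0.10 and DLL3, an inhibitory Notch ligand, at -0.33 ± 0.07. TGF-beta signalling rose with a median of 0.06 over 32 members (camera adjusted p = 0.0379, adjusted p = 0.651 with an estimated correlation), led by ID1 at 0.42 ± 0.12 and SMAD3 at 0.42 ± 0.14. The cell cycle list fell with a median of -0.02 over 48 members (camera adjusted p = 0.0483, adjusted p = 0.876 with an estimated correlation), and E2F1 was lower in 9 of 9 lines at -0.15 ± 0.03. Neither list had a member called over all genes, and adjusted over the list alone 0 members of the TGF-beta list passed and 1 of the cell cycle list fell.

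The other 14 lists did not pass in the shared response. Their camera adjusted p values were 0.157 for cholesterol synthesis, 0.182 for the interferon response, 0.418 for the neural transcription factors, 0.512 for epithelial genes and 0.492 each for the Notch pathway, DNA methylation and polycomb proteins, and the immune, fibroblast and endothelial markers. They were 0.697 for myeloid differentiation and for amino acid stress, 0.864 each for the tuft cell program, antigen presentation and cell cycle arrest with apoptosis, 0.870 for MYC and ribosome biogenesis, and 0.970 for LSD1 and its partners, of which HMG20B alone passed as a gene. Adjusted over the list alone, 3 Notch genes rose and 1 fell, 3 epithelial genes rose and 1 fell, 1 partner of LSD1 rose and 2 fell, 1 antigen presentation gene rose and 1 fell, 1 interferon gene fell, and 0 genes passed in the others. Median, mean and test differed in sign for the tuft cell, LSD1 partner, epithelial and antigen presentation lists. Members with opposite directions included NOTCH2 at 0.59 ± 0.17 and DLL3 in the Notch list. In antigen presentation they included B2M at 0.18 ± 0.04 and HLA-B at -0.23 ± 0.04. None of these passed over all genes. HLA-B was read from a probe set ending in _x_at, and whether its signal is specific to that gene was not tested.

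Over the same 6 lines, the shared response was compared between days. PTPN14 had means of 0.89, 1.25 and 1.21 at days 2, 4 and 7, VIM had 0.98, 1.11 and 1.43, and GRP had -0.57, -0.93 and -1.04. None of these passed with 6 lines, where limma called 0 genes on each day, with 1383, 1207 and 1519 genes at an unadjusted p below 0.05. From day 2 to day 7 the largest shift among those was -0.46 ± 0.19 for GRP and 0.45 ± 0.11 for VIM (SE, n = 6 lines, adjusted p = 0.750 for both). For that change limma called 0 genes, with 993 at an unadjusted p below 0.05, so no change of the shared response over time was detectable with this number of lines. Tested against the spread between arrays instead of between lines, 879, 1341 and 3033 genes passed on the 3 days and 56 passed for the change.

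**Figure D2:**
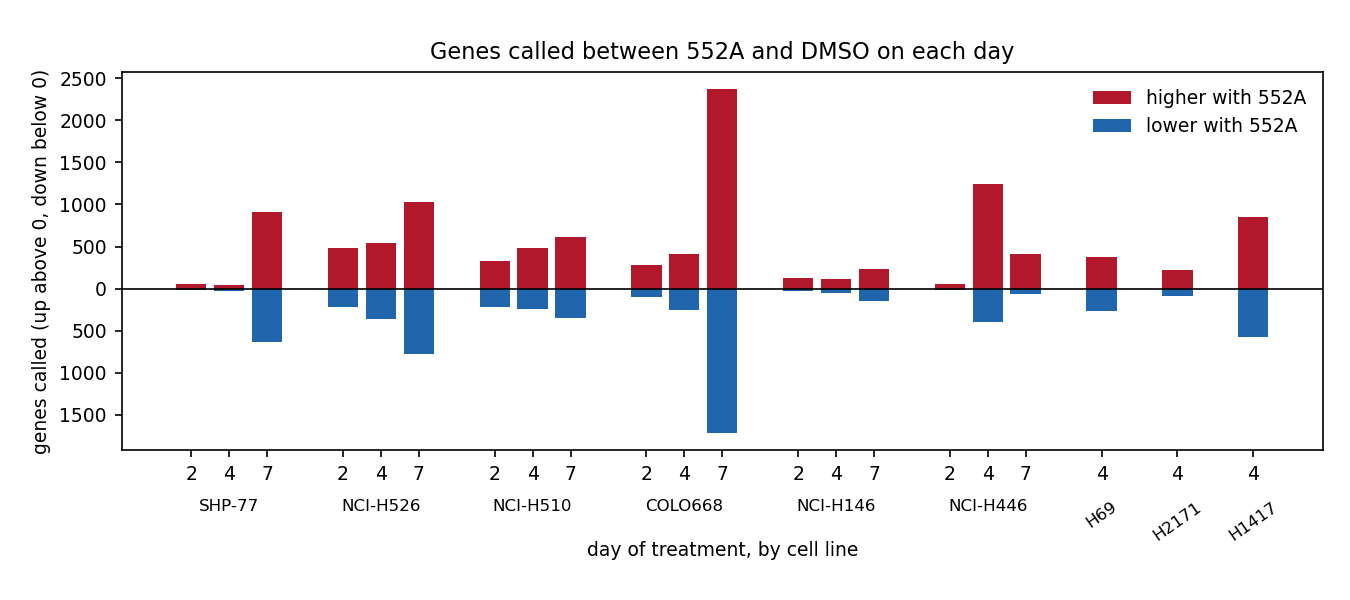
Number of genes called between 552A and DMSO (vertical axis, higher above 0 and lower below 0) on each day of treatment in each cell line (horizontal axis). COLO668 had 378, 657 and 4084 genes at days 2, 4 and 7, and NCI-H446 had 76, 1638 and 477.

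In SHP-77 the strongest change was PTPN14, which rose 3.75-fold (log2 1.91 ± 0.11, SE, 8 552A and 6 DMSO arrays, adjusted p = 9.63e-19). AGR2, a secretory pathway protein, rose by 1.63 ± 0.25 over the 3 days (adjusted p = 6.46e-06), although its changes of 1.36 at day 2 and 1.38 at day 4 did not pass alone. FRMD3 fell by 1.38 on the log2 scale (SE 0.11, adjusted p = 3.99e-14), as did NKX2-2 (SE 0.13, adjusted p = 2.69e-12). MYC changed by -0.39 ± 0.11 and CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 0.30 ± 0.08. In the mesenchymal list 9 members rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 2.22e-05, and 0.000562 with an estimated correlation), with ANXA3 at 1.40, TGFBI at 0.65 and FN1, fibronectin, at -0.74.

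Of the cell cycle genes in SHP-77, 13 fell and 0 rose (23 and 1 adjusted over the list alone; adjusted p = 3.65e-07, but adjusted p = 0.505 with an estimated correlation), with CENPE at -0.32 and FOXM1 at -0.25. In antigen presentation 4 members rose (6 adjusted over the list alone), among them PSMB9 at 0.42 and TAP1 at 0.28 (adjusted p = 0.000155, adjusted p = 0.0699 with an estimated correlation). The list of neural transcription factors fell (7 members down, 13 adjusted over the list alone), the DNA methylation and polycomb list fell (1 member down by both counts; adjusted p = 0.0486), and the interferon, epithelial and amino acid stress lists rose, all with adjusted p of at least 0.184 with an estimated correlation. In all 1249 genes passed in this line, 594 up and 655 down, and 67, 77 and 1541 passed on days 2, 4 and 7. At day 7 the ACTB 3' minus 5' signal, a sign of RNA integrity, averaged 1.00 in DMSO and 0.54 in 552A arrays, against -0.04 and 0 at day 4. The count was 696 without DMSO day 7 replicate 1, 2097 without DMSO day 7 replicate 2, 721 without 552A day 2 replicate 2 and 1397 without the 6 arrays in doubt.

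In NCI-H526, the line with high POU2F3, IGFBP2, a carrier of insulin-like growth factors, rose 13.9-fold (log2 3.80 ± 0.09, SE, 7 552A and 6 DMSO arrays, adjusted p = 5.94e-39). SEPTIN10 rose 13.4-fold (3.74 ± 0.07, adjusted p = 9.76e-43). CCN3, a secreted matrix protein, fell by 3.11 on the log2 scale (SE 0.16, adjusted p = 1.65e-23), and LUM, the collagen-binding proteoglycan lumican, fell by 2.01 (SE 0.15, adjusted p = 6.1e-16). ZEB1 rose by 3.14 ± 0.08 from a DMSO level of 4.57 ± 0.18 (SD, n = 6). An arm of SEPTIN10, ZEB1 and TMEM163 was dim in this line, so their changes may be lower limits. Both arms of LUM lay below 6.09, at 5.98 under DMSO and 3.97 with the change added. The fall of LUM was therefore read from dim signals only. POU2F3 itself changed by -0.20 ± 0.07 (adjusted p = 0.0228), while GFI1B rose by 0.52 ± 0.06 and INSM1 by 0.37 ± 0.06. POU2AF1 and POU2AF3, coactivators of POU2F3, rose by 0.56 and 1.06. The tuft cell list as a whole did not pass in this line (camera adjusted p = 0.524, adjusted p = 0.871 with an estimated correlation). Of its members 5 rose and 7 fell (6 and 9 adjusted over the list alone), with a median of -0.09.

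The cell cycle list rose in NCI-H526, with 11 members up and 0 down (13 and 0 adjusted over the list alone; adjusted p = 0.00197, adjusted p = 0.823 with an estimated correlation), among them CENPF at 0.42 and E2F2 at 0.33. Of the amino acid stress genes 12 fell and 3 rose (13 and 4 adjusted over the list alone), with the cystine transporter SLC7A11 down 2.01-fold and PHGDH, the entry enzyme of serine synthesis, at 1.01 (adjusted p = 0.0486, adjusted p = 0.889 with an estimated correlation). In cholesterol synthesis 7 members fell, also adjusted over the list alone, with SREBF1 at -0.60 (adjusted p = 0.0271, adjusted p = 0.713 with an estimated correlation). Neural transcription factors, TGF-beta signalling (LTBP1 at 1.47) and the interferon response (HERC5 at 1.02) rose as lists with adjusted p of 0.0209, 0.0150 and 0.0193, and with an estimated correlation their adjusted p values were 0.505, 0.287 and 0.354. In this line 3245 genes passed, 1636 up and 1609 down, and on single days 706, 908 and 1805 did. LUM did not pass when no filter was set on dim probe sets, since another of its probe sets was then used, with -0.02.

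In NCI-H510 mesenchymal genes rose and neuroendocrine genes fell. VIM rose by 2.51 ± 0.10 (SE, 6 552A and 6 DMSO arrays, adjusted p = 8.55e-28) and ZEB1 by 2.13 ± 0.09, and 18 of 38 mesenchymal genes rose with 0 down (19 and 1 adjusted over the list alone; adjusted p = 5.76e-11, and 7.16e-07 with an estimated correlation). The others of the largest were the galectin LGALS3 at 1.66 and YAP1, a transcriptional coactivator, at 1.36. Of 29 neuroendocrine markers 14 fell and 0 rose (17 and 0 adjusted over the list alone; adjusted p = 9.03e-14, and 0.0115 with an estimated correlation), with GRP at -1.29, the granin SCG2 at -0.99 and CALCA at -0.93. The neuropeptide precursor ADCYAP1 fell by 2.46 on the log2 scale (SE 0.12, adjusted p = 3.98e-23) and KCTD12, a subunit of GABA-B receptors, fell by 2.14 (SE 0.14, adjusted p = 1.83e-18).

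The largest increases in NCI-H510 were LRRN4 at 2.52 ± 0.12 (adjusted p = 2.28e-24) and the adhesion receptor ADGRG6 at 2.52 ± 0.10 (adjusted p = 1.64e-27). MYC rose by 0.97 ± 0.12, HES1, a Notch target, by 0.96 ± 0.12, and the death receptor TNFRSF10B by 2.15 ± 0.12. TNFRSF10B led the apoptosis list, of which 7 members rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0444, adjusted p = 0.617 with an estimated correlation). TGF-beta signalling rose with TGFBI at 1.31 and ID1 at 1.25, the interferon list rose with IFITM3 at 1.22, and neural transcription factors fell with ST18 at -1.97, although ISL1 rose by 2.20. With an estimated correlation their adjusted p values were 0.285, 0.505 and 0.505. In this line 2308 genes passed, 1320 up and 988 down (539, 722 and 968 on single days), 3811 from its own arrays alone and 3502 without the 6 arrays in doubt, none of which belongs to this line.

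In COLO668 CYP4X1, a cytochrome P450, rose 14.9-fold (log2 3.90 ± 0.12, SE, 6 552A and 6 DMSO arrays, adjusted p = 1.42e-32). Its DMSO level of 5.18 was dim, so this change may be a lower limit. LBH, a transcriptional cofactor, rose by 2.41 ± 0.12 (adjusted p = 3.94e-23). GRP fell by 1.90 on the log2 scale (SE 0.19, adjusted p = 7.4e-12) and TMEM163, a zinc transporter, fell by 1.22 (SE 0.10, adjusted p = 2.58e-14). NOTCH1 and NOTCH2 rose by 1.14 ± 0.10 and 1.08 ± 0.11, and HES1 by 1.00 ± 0.12. The Notch list itself did not pass, with 7 members up and 3 down (camera adjusted p = 0.188, adjusted p = 0.548 with an estimated correlation). In the mesenchymal list 19 members rose and 1 fell (22 and 1 adjusted over the list alone; adjusted p = 9.15e-06, and 0.000421 with an estimated correlation), with ZEB1 at 1.25 and SNAI2 at 0.98. Of the neuroendocrine markers 13 fell and 3 rose (14 and 3 adjusted over the list alone; adjusted p = 0.00843, adjusted p = 0.54 with an estimated correlation). INSM1 rose by 0.34 ± 0.06.

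In the list of LSD1 and its partners, which also holds the amine oxidases MAOA and MAOB, 10 members rose in COLO668 and 2 fell (13 and 3 adjusted over the list alone), with ZNF217 at 1.19 and MAOB, an enzyme related to LSD1 and no partner of it, at 0.84 (adjusted p = 0.00337, adjusted p = 0.505 with an estimated correlation). TGF-beta signalling, with 14 members up and 3 down over all genes and over the list alone, and the interferon list, with 8 up and 1 down over both, rose at adjusted p of 0.00337 and 0.0457, and amino acid stress and myeloid genes (LMO2 at -0.58) fell. With an estimated correlation the adjusted p values of these were 0.184, 0.505, 0.871 and 0.285. The line had 3248 genes called, 1895 up and 1353 down, a share of 58.3% up that became 46.0% after quantile normalization. The single days had 378, 657 and 4084 genes. The ACTB 3' minus 5' signal at day 7 averaged 0.70 in DMSO and 0.96 in 552A arrays, against 0.22 and 0.30 at day 4, and 4372 genes passed without the 6 arrays in doubt.

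In NCI-H146 FRZB, a secreted Wnt antagonist, rose by 2.46 ± 0.12 (SE, 6 552A and 6 DMSO arrays, adjusted p = 1.57e-23) and VIM by 2.08 ± 0.10 (adjusted p = 1.57e-23). NKX2-2 fell by 2.00 on the log2 scale (SE 0.13, adjusted p = 7.69e-18) and PDGFRA, a growth factor receptor, fell by 1.60 (SE 0.09, adjusted p = 1.73e-20). NOTCH2 rose by 1.93 ± 0.11 and ANXA3 by 1.82 ± 0.13. Epithelial genes rose as a list, with 7 up and 0 down over all genes and over the list alone, among them OVOL2 at 0.90 and OVOL1 at 0.83 (adjusted p = 0.000159, adjusted p = 0.114 with an estimated correlation). The mesenchymal list, with 7 up and 1 down by both counts, had an adjusted p of 0.0150 (adjusted p = 0.073 with an estimated correlation). Neural transcription factors (4 down and 1 up) and the cell cycle list (0 members called by limma over all genes or over the list alone) fell at adjusted p of 0.0124 and 0.0178, and adjusted p = 0.505 and 0.889 with an estimated correlation. Here 981 genes passed, 655 up and 326 down (160, 167 and 379 on single days), and 1727 passed without the 6 arrays in doubt, none of them from this line. PDGFRA did not pass without a filter on dim probe sets, when another probe set gave -0.16.

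In NCI-H446 LUM rose by 1.90 ± 0.15 (SE, 6 552A and 7 DMSO arrays, adjusted p = 3.88e-14) and the small heat shock protein CRYAB by 1.83 ± 0.12 (adjusted p = 1.9e-17). The netrin receptor UNC5A fell by 1.40 on the log2 scale (SE 0.09, adjusted p = 4.8e-17) and HEPACAM2 fell by 1.38 (SE 0.12, adjusted p = 4.38e-13). In the mesenchymal list 11 members rose and 2 fell (12 and 3 adjusted over the list alone; adjusted p = 0.00374, and 0.0248 with an estimated correlation), with MYOF at 1.64, VIM at 1.33 and SNAI2 at 1.08. The collagen gene COL1A1, in the fibroblast markers, rose by 0.41 ± 0.10. The neural transcription factors (2 members up and 2 down) fell as a list and the amino acid stress genes (1 of 32 up, 0 down) rose as a list at adjusted p of 0.0324 and 0.0138, with adjusted p = 0.54 and 0.823 with an estimated correlation. In all 858 genes passed, 661 up and 197 down, a share of 77.0% up that became 62.4% after quantile normalization, and 76, 1638 and 477 passed on days 2, 4 and 7. DMSO day 4 replicate 2 had an interquartile range of 2.56. The count was 2087 without DMSO day 4 replicate 1, 1108 without the 6 arrays in doubt and 220 from the line's own arrays alone, and LUM did not pass without a filter on dim probe sets, at 0.10.

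H69 was measured at day 4 only, with 2 arrays per arm. EFEMP1, an extracellular matrix protein, rose by 2.34 ± 0.20 (SE, adjusted p = 3.56e-13) and CYB5R2 by 2.29 ± 0.16 (adjusted p = 1.11e-15). GNG8, a G protein subunit, fell by 2.74 on the log2 scale (SE 0.13, adjusted p = 3.58e-23) and NKX2-2 fell by 1.99 (SE 0.23, adjusted p = 3e-09). ZEB1 rose by 1.54 ± 0.15 and the Notch ligand DLL1 by 1.46 ± 0.20. Mesenchymal genes rose, 5 up and 0 down (7 and 0 adjusted over the list alone; adjusted p = 0.000147, and 0.00168 with an estimated correlation), with LGALS3 at 1.43 and the annexin ANXA1 at 1.05. The list of neural transcription factors fell, 4 down and 1 up by both counts (adjusted p = 0.0433, adjusted p = 0.548 with an estimated correlation). Of 641 called genes 375 rose and 266 fell. Without any 1 of its 4 arrays the count was 328 to 381 (328 and 344 without 552A replicates 1 and 2, 381 without DMSO replicate 1), and without the 6 arrays in doubt it was 1070.

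H2171, also with 2 arrays per arm at day 4, had 308 called genes, 220 up and 88 down. PLEKHB1 rose by 2.06 ± 0.20 (SE, adjusted p = 1.06e-10), and DLL1 rose by 1.87 ± 0.20. CHRNA3 fell by 2.08 on the log2 scale (SE 0.15, adjusted p = 6.03e-15) and CHRNB4, its neighbour in a cluster of nicotinic receptor genes, by -1.95 ± 0.13 (adjusted p = 4.87e-17). The immediate early gene FOS rose by 2.02 ± 0.52 (adjusted p = 0.0195), but without DMSO replicate 1 it had 0.85 (adjusted p = 0.898), and at 1.96 and 2.08 without either 552A array (adjusted p = 0.194 and 0.128) and at 2.02 from the line's own arrays alone (adjusted p = 0.279) it did not pass either. Epithelial genes rose as a list, 3 up and 0 down (6 and 0 adjusted over the list alone), with OVOL2 at 1.27 and KRT19 at 0.81 (adjusted p = 0.000949, adjusted p = 0.184 with an estimated correlation). The mesenchymal list (SNAI2 at 1.41; 2 up, 5 adjusted over the list alone) rose and the amino acid stress list (SLC7A11 at -0.87; 1 down, 3 adjusted over the list alone) fell, at adjusted p of 0.0209 and 0.00137, with adjusted p = 0.102 and 0.632 with an estimated correlation. The count was 199 and 165 without DMSO replicates 1 and 2, 151 and 154 without 552A replicates 1 and 2, 143 from the line's own arrays alone and 662 without the 6 arrays in doubt.

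H1417, again with 2 arrays per arm at day 4, had 1419 called genes. NKX2-2 fell by 5.40 on the log2 scale (SE 0.23, adjusted p = 9.49e-26) from a DMSO level of 10.66 ± 0.26 (SD, n = 2). It ended near its lowest DMSO mean in any line, 5.06, so the measured fall may be a minimum. Further, PTPRM, a receptor phosphatase of cell contacts, fell by 2.70 (SE 0.18, adjusted p = 4.56e-17). LBH rose by 3.33 ± 0.21 (adjusted p = 1.59e-18) and SORCS3, a neuronal sorting receptor, by 2.83 ± 0.14 (adjusted p = 4.88e-23). Members of the Notch list were called with NOTCH1 at 1.40 ± 0.17, HES1 at 1.90 ± 0.21 and JAG1 at 1.49 ± 0.18, although the list itself did not pass (adjusted p = 0.115). GRP changed by -2.17 ± 0.33 and CHGA by -0.93 ± 0.09, in a neuroendocrine list with 4 down and 1 up (5 and 1 adjusted over the list alone; adjusted p = 0.0209, adjusted p = 0.611 with an estimated correlation). Of the cell cycle genes 9 fell and 0 rose (17 and 2 adjusted over the list alone), with CCNA2 at -0.46 and BUB1 at -0.42 (adjusted p = 1.35e-07, adjusted p = 0.505 with an estimated correlation). CDKN1A rose by 0.58 ± 0.15. Of the called genes 849 rose and 570 fell, with 920 without 552A replicate 2, 930 without DMSO replicate 2, 577 from the line's own arrays alone and 2324 without the 6 arrays in doubt.

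**Figure D3:**
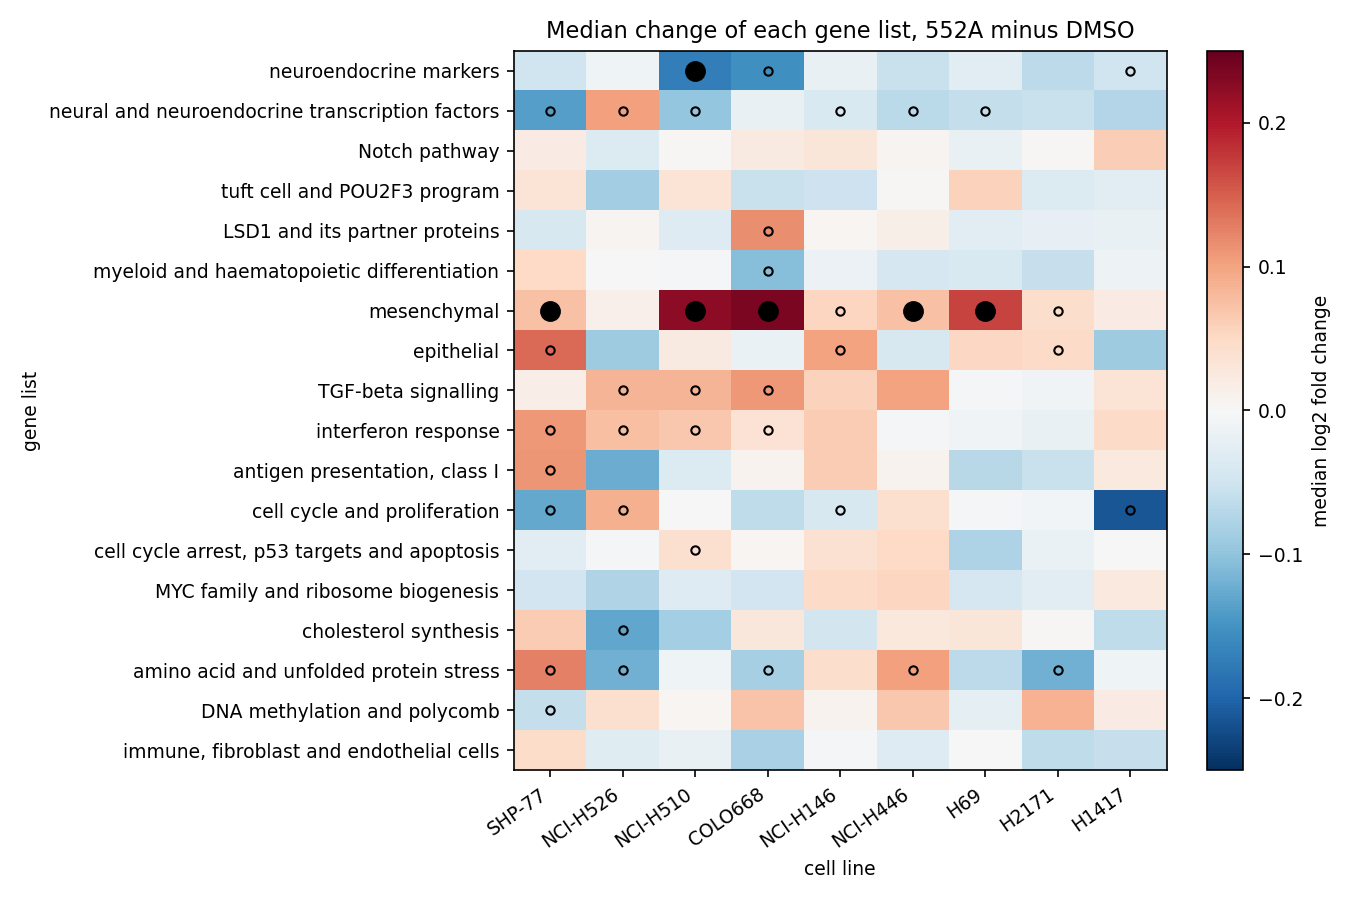
Median log2 fold change (colour) of the members of 18 gene lists (vertical axis) in 9 cell lines (horizontal axis). Open dots mark lists called by camera with the preset correlation, 41 of 162, and large filled dots the 6 that were also called with an estimated correlation, 5 of them for the mesenchymal list.

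The last comparison asked where the lines differed in their response. By the F test, 5842 genes had unequal effects in the 6 time course lines. The 6 genes named by range were CYP4X1 at 3.94 (adjusted p = 1.07e-27), IGFBP2 at 3.93 (adjusted p = 7.24e-34), CCN3 at 3.93 (adjusted p = 1.07e-20), LUM at 3.90 (adjusted p = 9.89e-20), TMEM163 at 3.74 (adjusted p = 1.78e-27) and SEPTIN10 at 3.55 (adjusted p = 5.84e-34). Those of CYP4X1, TMEM163 and SEPTIN10 may be lower limits because 1 arm was dim. The range of LUM includes its fall in NCI-H526, where both arms were dim. The order of the 6 cannot be read from these ranges. TMEM163 rose by 2.52 ± 0.10 in NCI-H526 and fell in COLO668, and LUM fell in NCI-H526 and rose in NCI-H446. LUM did not pass without a filter on dim probe sets (adjusted p = 0.407). The F count was 690 without replicate 1 and 663 without replicate 2 of every group, since most groups then held 1 array.

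ZEB1 differed between these lines (range 3.30, adjusted p = 6.98e-32), and its changes stood beside different starting levels. It rose in NCI-H526, NCI-H510, COLO668, H69 and H1417, whose DMSO levels lay between 4.57 and 7.03. It did not pass in SHP-77, H2171 and NCI-H446, whose DMSO levels were 10.27, 10.15 and 11.91, nor in NCI-H146, where the DMSO level of 4.20 was the lowest of the 9 lines and the change was 0.17 ± 0.09. VIM differed as well (range 2.26, adjusted p = 8.39e-23) and rose in 6 of the 9 lines. MYC, with a range of 1.36 (adjusted p = 5.37e-08), rose in NCI-H510 and fell in SHP-77. KDM1A (adjusted p = 0.338) and REST (adjusted p = 0.480), a repressor of neuronal genes, did not pass. For REST this rests on 1 probe set, with a mean ratio of 0.06 at day 4, while a second and dimmer probe set had 0.97 (1.98 in NCI-H510 and 1.93 in COLO668), and the mean of both, 0.52, had an adjusted p of 0.118 in the shared test.

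Across genes, the day 4 responses of 2 lines correlated weakly. The median Pearson r over the 36 pairs of lines was 0.127, from -0.086 for SHP-77 with NCI-H446 to 0.382 for NCI-H510 with COLO668. Genes are not independent replicates, so r describes these arrays. Each line had its own DMSO arrays, and NCI-H510 and COLO668 shared 188 genes called in the same direction and 5 in opposite directions, where independent lists of these sizes would share 16.7. The spread of each gene was pooled over all lines, so a gene of low spread is called more easily in each line. The 16.7 does not allow for this and may be too low. Within a line the effects at days 2 and 4, from separate arrays, correlated at 0.461 to 0.824, and in NCI-H446 those at days 2 and 7 and at days 4 and 7 correlated at 0.226 and 0.019.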

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

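Of the tests in this part, only the comparisons of correlations between days of a line with those between lines were chosen after their results were seen. The tests of the day 7 counts and of NCI-H446 were designed once those patterns had been seen, with the outcome predicted before each was run, and the splits were predicted beforehand as well.

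At day 4 HMG20B had a ratio of -0.027 in H2171, while the other 8 lines lay between -0.375 and -0.265, a gap larger than Dixon's limit. A second and dimmer probe set of HMG20B had -0.122 in H2171, -0.131 in NCI-H510 and -0.071 in NCI-H446, so H2171 did not stand apart there. The first was the only such value in 29 groups tested, where chance gives 1.45. By the F test 5842 genes differed between the 6 time course lines, and of the named genes the ranges of effects were 3.94 for CYP4X1, 3.93 for IGFBP2 and CCN3, 3.90 for LUM, 3.74 for TMEM163, 3.55 for SEPTIN10, 3.30 for ZEB1 and 2.26 for VIM. They were 1.36 for MYC, 1.11 for HES1, 1.07 for NOTCH1, 0.67 for GFI1B, 0.53 for MYCL, 0.52 for INSM1, 0.50 for GFI1, 0.45 for CDKN1A (adjusted p = 0.0204) and 0.35 for POU2F3 (adjusted p = 0.0422). The DMSO level of POU2F3 lay below 6.09 in every line but NCI-H526, so its range sets that line against dim signals.

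The jump in called genes at day 7 in SHP-77 (77 to 1541 from day 4) and in COLO668 (657 to 4084) came with 5 arrays of raised ACTB 3' minus 5' signal, so noise tied to RNA integrity was weighed. With the day 7 arrays of low signal alone 198 genes passed in SHP-77 and 2506 in COLO668, against at most 34 and 350 from as many arrays at day 4, which is the outcome written down for a cause other than this noise. That outcome was a wrong criterion, since these counts rest on 1 DMSO array in each line and, in COLO668, on 1 552A array, with other groups supplying the spread, and the low 552A array of COLO668 still had a signal of 0.59 against 0.30 in DMSO. With the signal class as a block the day 7 counts were 1873 and 4264, but a block removes a shift between classes and not noise, so integrity stays open for both lines. Longer exposure, which the design names, stays open as well and was not tested apart from the sampling day. In the order of the series, SHP-77 DMSO day 7 replicate 1 stands apart, earlier than DMSO replicate 2 and all 552A arrays of that day. COLO668 DMSO day 7 replicate 2 stands apart, later than the other day 7 arrays of its line. The labels name no batch, so a batch tied to this order stays open and was not tested.

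NCI-H446 had 1638 called genes at day 4, more than at day 2 or 7, and its day 4 and day 7 effects correlated at 0.019 across genes. Without DMSO day 4 replicate 2, the array with a narrow spread of values, 512 genes passed at day 4 and 707 at day 7, so this array is a candidate cause of the day 4 excess. Leaving out another DMSO array of that day, which leaves as many arrays, gave 5891 (replicate 1) and 1970 (replicate 3), so fewer DMSO arrays alone do not account for the drop, although leaving out a 552A array gave 397 or 475. The 5891 genes came from DMSO replicates 2 and 3, whose ACTB 3' minus 5' signals were 0.22 and 0.18. DMSO replicate 1 had -0.05 and the 552A arrays had 0.01 and -0.04. The narrow array is therefore not shown to be the only cause. In the order of the series, DMSO replicates 2 and 3 stand apart, later than DMSO replicate 1 and the 552A arrays of that day. The labels name no batch, and a batch or other feature shared by replicates 2 and 3 was not tested. The low correlation is another matter, since without the narrow array it was 0.086, still under the lowest of the other lines, 0.434. A change of the response between days stays open, and 6 of 100 splits that exchanged treatment labels within days called at least the 858 genes of the real one, up to 3648, so chance could not be excluded and the higher counts point to a structure of these arrays other than treatment.

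The weak correlation between lines (median r = 0.127) was set against noise between arrays. In 6 of 6 time course lines the effects at days 2 and 4, from separate arrays, correlated better than the best of the 36 pairs of lines, 0.382. Days 2 and 7 and days 4 and 7 did so too in 5 lines, which argues against array noise as the whole cause there, but not in NCI-H446 (0.226 and 0.019), where noise stays open. Exchanging treatment labels within lines gave a median r of at most 0.029 and reached the real value in only 1 of 100 splits, the real one. Differences between the lines themselves stay open, and no label gives a class that could be tested.

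Splits of the arrays or turned signs were run for the other counts. In SHP-77 (1249 genes, highest other split 441), NCI-H526 (3245, highest 2855), NCI-H510 (2308, highest 1125) and COLO668 (3248, highest 2605), 1 of 100 splits, the real one, reached the count. The same held for NCI-H146 (981, highest 498), the F test (5842, highest 1922) and the shared response at day 4 (8, highest 0). This argues against a chance assignment of labels to these arrays, or of signs to these lines. The splits of arrays exchange arrays that may share a culture, so they cannot exclude chance differences between cultures. Chance was not excluded for the 4 called lists, since 37 of 100 sign patterns over lines called as many and up to 7. For the shared response in 6 lines at days 2, 4 and 7 and its change, limma called 0 genes in all 32 sign patterns.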

How the results depend on the processing

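The removal of the 6 arrays and the ACTB covariate were tests chosen after the array values were seen. Across settings other than leaving out a single line or array, 113 of 148 counts stayed within 1.5 times their value and 35 did not, and of 474 values of called named genes 462 kept direction and call and 12 lost the call. Of 486 values of named genes that had not passed, 69 passed and 3 changed sign. With a single line or array left out, 117 of 143 counts stayed within that bound, and 383 of 448 called values kept their call while 65 lost it. Where the cause is not named below, the cause was not tested.

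The 8 shared genes of day 4 became 13 with no filter, 20 with the strict filter, which tested 12861 genes, 16 with the mean of probe sets and 2043 at array level, which ignores the spread between lines, and 0 to 6 with a line left out. At array level the 6 lines gave 879, 1341 and 3033 genes at days 2, 4 and 7 and 56 for the change, and day 4 gave 1 without NCI-H446 and 0 otherwise. The 4 called lists became 1 with the estimated correlation, 2 with the strict filter and 2 to 5 with a line left out (2 without SHP-77).

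Single days, with fewer arrays, gave 67 and 77 genes (SHP-77, days 2 and 4), 706, 908 and 1805 (NCI-H526, days 2, 4 and 7), 539, 722 and 968 (NCI-H510), 378 and 657 (COLO668, days 2 and 4), 160, 167 and 379 (NCI-H146) and 76, 1638 and 477 (NCI-H446). A line's own arrays gave 3811 in NCI-H510, 220 in NCI-H446, 143 in H2171 and 577 in H1417. Without the 6 arrays 3502 passed in NCI-H510, 1727 in NCI-H146, 1070 in H69, 662 in H2171 and 2324 in H1417. None of the 6 belongs to these lines, so their counts moved only through the spread pooled over all lines. Leaving out single arrays gave 696 to 2097 in SHP-77, 618 to 2087 in NCI-H446, 328 to 381 in H69, 151 to 199 in H2171 and 920 to 1065 in H1417. The F test gave 663 to 6257 with the arrays of 1 replicate number left out, where leaving out replicate 1 (690) or 2 (663) leaves most arms with 1 array.

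Same-numbered arrays did not deviate together consistently, with a mean r above 0.1 in 10 of 21 lines and days (-0.405 to 0.488), so the numbers were not taken to pair samples. With the replicate block 1619, 3424, 2577, 3650, 1147 and 1227 genes passed in the time course lines in the order above, and 759, 413 and 1655 in H69, H2171 and H1417, each within 1.5 times.

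HLA-F changed sign from -0.14 ± 0.04 to 0.038 with no filter. Ratios near 0 changed sign as well: GFI1B was 0.019 and MYCN -0.015 with the mean of probe sets. With a line left out MYCN ranged from -0.026 to 0.06 and GFI1 from -0.051 to 0.016. Dim probe sets limit LUM and PDGFRA, whose calls ended with no filter.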

Other observations

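The test of recurrence against independent lists in this part was chosen after its result was seen. At day 4, 47 genes were called in the same direction in at least 5 of 9 lines, 42 up and 5 down. NCI-H446 gave the most calls of the 9 lines, 1638, against 512 without its narrow array, DMSO day 4 replicate 2. How many of the 47 genes, the examples below included, rest on this line was not counted. Of the 47 genes the rule had named 11, among them PTPN14, ZEB1 and HMG20B, and 36 it had not. The examples that follow are from the 36 and were chosen after their values were seen. ZFP36L1, which destabilises messenger RNAs, and LIX1L were called up in 6 lines with mean ratios of 0.78 each, and so were the kinase RIPK2 and the tight junction protein OCLN at 0.37 and 0.36. SGK1, a kinase of the AGC family, rose in 5 lines with a mean of 0.59, AMOTL2, a binding partner of YAP, rose in 5 with 0.63, and MICB, a ligand for a receptor of natural killer cells, rose in 5 with 0.64. PHLDB2 was called down in 6 lines at a mean of -0.54, and TFEB, a regulator of lysosome genes, in 5 at -0.57.

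Independent lists of the same sizes, drawn at matched signal levels, gave 0.042 such genes on average and at most 2 in 1000 draws. The draws did not allow for the spread of each gene, pooled over all lines, by which some genes are called more easily in every line. The 47 genes therefore argue only against such independent lists. A part of the response common to most lines is a hypothesis they allow, although the test with lines as replicates called only 8 genes. Probe sets that merely vary more than others in every line would move in directions independent between lines. When the directions of whole lines were turned, 1 of 256 sign patterns, the real one, gave 47 genes, and the others gave a median of 4 and at most 42, which argues against that explanation. Features of the array with a direction common to all lines were not tested.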
